A study of Mus musculus with 34 samples.

How the data were processed

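Messenger RNA was sequenced from liver, hindlimb muscle and pancreas of newborn C57BL/6 mice with or without Escherichia coli infection. The animals were wild-type (WT) or lacked the alpha chain of the interleukin-27 receptor (KO), per the labels. The set held 34 libraries, 12 from liver, 11 from muscle and 11 from pancreas. Per the labels' protocols, tissue was homogenised in TRI Reagent, RNA was purified on columns, and libraries were built with a KAPA mRNA HyperPrep kit. Groups and replicate numbers came from the sample titles and characteristics. The labels do not say that each library came from a separate animal, so p-values measure the spread between these libraries, which may in part be technical.

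The authors deposited 1 table of 21073 genes with an Entrez gene ID and a symbol each. Its values are log2 of RPKM (reads per kilobase of gene length, scaled to library size) plus 1, with 0.0001 added after the log, as the values deposited by the authors show. Per the submitters' processing notes, reads were counted per gene with featureCounts of the Subread package on mm10. Versions, the annotation release and the strand setting are not given in the sources used here. Values of overlapping, antisense and near-identical genes (Saa1 and Saa2, Ins1 and Ins2, Reg3 genes, haemoglobin genes) are uncertain for that reason. The design had assumed RPKM on a linear scale. The log was undone before any step, and the tests stayed as planned.

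RPKM steps were searched for whole reads with a length per gene. For 19163 genes a length was found that gave whole reads, with 99.8% to 99.9% of a library's values within 0.05 of a whole read. The depth recovered in this way was 3.95 to 18.78 M reads per library. In a 2 kb gene, 1 read was worth 0.027 to 0.127 RPKM, depending on the library. Reads recovered over genes summed to 109.3% to 115.2% of that total, and the reason is not given in the sources used here. The 3 infected WT liver libraries had the highest sums, 114.4%, 115.2% and 115%, and the highest of the other libraries had 113.5%. Since RPKM is not a count, these reads served only for depth and for added alternatives. No pair of libraries within a group held identical values. Gene names were compared with RefSeq for GRCm38.p6, the assembly behind mm10. Of all gene IDs, 20857 matched and 20247 carried the same symbol there. The table listed 170676 values at its smallest value, written here as 0.

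Each tissue was analysed by itself in R 4.3.3 with limma 3.58.1. RPKM values were divided by median-of-ratios size factors, and log2(scaled RPKM + 0.5) was fitted with 1 mean per group. Fold changes are therefore on the log2(value + pseudocount) scale, which understates changes of low genes. A gene was tested where at least 2 libraries of the tissue reached an RPKM of 1. Empirical Bayes moderation used the mean-variance trend. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in that comparison. Per tissue the comparisons were infection in WT, infection in KO, KO minus WT in controls, KO minus WT in infected animals, and the difference of the infection effects. Il27ra was compared with an exact permutation test over libraries of a tissue. Errors of log2 changes are standard errors, and errors of levels are standard deviations.

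Gene lists, 46 in number, were written before the data were examined, as were the groups, the tests, the first alternatives and the rule for named genes. Each list with at least 4 tested genes went through camera of limma with a preset correlation of 0.01, in 660 tests. Of these, 300 had an adjusted p under 0.05, and 12 of the 300 kept it with the correlation estimated per list. List members that passed are counted over all genes tested, and in brackets when adjusted over the list alone. Named genes were the calls with the largest log2 change whose libraries did not overlap between the groups, 6 per direction for infection in WT and both KO minus WT comparisons. For infection in KO, 3 further genes per direction were taken, and 5 per direction for the difference of effects, without the overlap condition. Unnamed gene models were left out of the ranking, and 2 genes that the rule picks are not reported here. Up to 4 members with the smallest adjusted p were named from lists described. With under 5 calls, the 3 genes per direction with the smallest p are given as values. Il27ra, Il27, Ebi3, Il6st and Ddx3y were always named, and Xist is not analysed here.

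The procedure was tested on simulated data built from each tissue's gene means and residual spread, with 200 changed genes per comparison. For infection in WT liver (12484 genes run), 71 of 100 genes changed by 1 on the log2 scale and 99 of 100 changed by 2 were recovered. The same figures were 46 and 78 for infection in KO muscle (13362 genes run), and 11 and 51 for the difference of effects in pancreas (15138 genes run). In 15 simulated comparisons, a list of 20 genes raised by 1 was called 15 times, and 0 of 660 unchanged lists were called. The simulated noise was independent between genes, so this says nothing of false calls for lists whose genes move together.

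Alternatives planned beforehand were pseudocounts of 0.1 and 1, no filter, RPKM as deposited, quantile normalization, array quality weights, Ddx3y as covariate, a replicate block, the style of the library name as a batch term in muscle, fits of the 2 groups alone, and leaving out each library in turn. Where this leaves 1 library in a group, the spread comes from the other groups of that tissue. After seeing the data, limma voom on the recovered reads, thinning to the smallest library, removal of a lowess trend over gene length, marker levels as covariates (cartilage and bone in muscle, glandular stomach in pancreas), and leaving out doubtful libraries were added. Marker lists of glandular stomach, squamous epithelium, smooth muscle and milk proteins were also written after the data were seen. Data preparation and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.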

Results

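Gene expression was measured by RNA sequencing in liver, hindlimb muscle and pancreas of neonatal mice, to ask how interleukin-27 signalling bears on metabolic fitness during Escherichia coli sepsis. Interleukin-27 is a cytokine of the interleukin-6 family that signals through Il27ra and Il6st. Each tissue had uninfected controls and infected animals of both genotypes. Every group held 3 libraries, except infected WT pancreas and infected KO muscle with 2 each. Where a time is given in the labels, infected tissue was taken at 24 h. Depth in M reads per library was 4.88 to 10.04 in liver, 3.95 to 10.75 in muscle and 10.13 to 18.78 in pancreas. The titles of all 5 infected KO libraries of liver and muscle carry the wording Ec-low, which no WT title carries, and its meaning is not given. Genotype and that wording cannot be separated in these 2 tissues. In pancreas the titles of infected libraries of both genotypes carry Ec.

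Il27ra, the gene targeted in the KO animals, lies on chromosome 8 at 84030286 to 84042600 of GRCm38 (mm10). Its level was higher in the libraries labelled KO than in those labelled WT. In pancreas the 6 libraries labelled KO held 4.61 ± 1.53 scaled RPKM and the 5 labelled WT 0.589 ± 0.0843 (exact permutation p = 0.00216, adjusted over 3 tissues 0.00648). Muscle showed 2.35 ± 1.04 in 5 KO-labelled and 0.802 ± 0.422 in 6 WT-labelled libraries (exact permutation p = 0.00866, adjusted 0.013). In liver the values were 1.91 ± 0.616 and 1.35 ± 0.435 in 6 libraries each (exact permutation p = 0.0952, adjusted 0.0952). The muscle and pancreas values go against the labels if they read the deleted part. A value over the whole gene can lie outside the deleted part, and then it checks nothing. Groups are therefore named below by their labels, and every direction between genotypes rests on those labels.

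**Figure D1:**
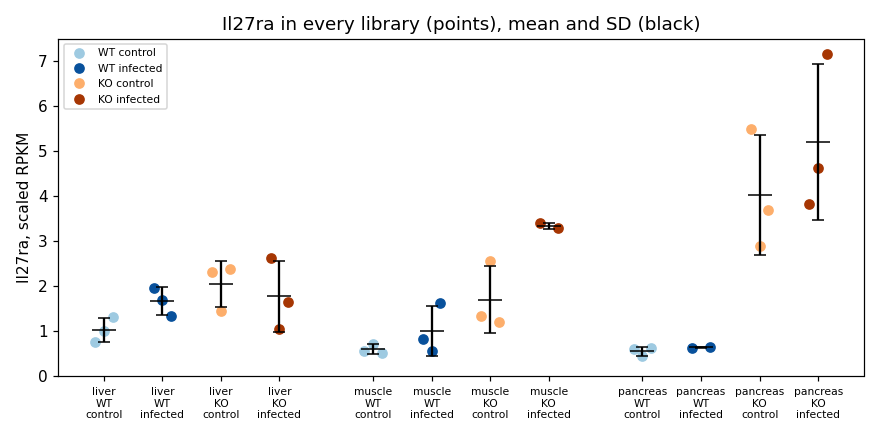
Scaled RPKM of Il27ra on a linear axis, 1 point per library, grouped by tissue, genotype label and infection, with the mean and SD of each group in black. Pancreas libraries labelled KO average 4.61 and those labelled WT 0.589.

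Infection was associated with a large acute phase response in WT-labelled liver. All 27 tested acute phase genes rose, with a median log2 change of 2.57 (27 adjusted over the list alone; camera adjusted p = 8.12e-22). Saa1 rose from 2.98 ± 0.816 to 11590 ± 690.8 scaled RPKM (log2 change 11.72 ± 0.18, adjusted p = 3.84e-15, n = 3 per group), and Saa2 by 12.96 ± 0.38. Saa3 rose by 11.33 ± 0.34, and the orosomucoid genes Orm1 and Orm2 by 10.02 ± 0.31 and 10.35 ± 0.25. Of 20 tested inflammatory cytokines and chemokines 19 rose (19 adjusted over the list alone), among them Cxcl2 by 5.57 ± 0.24, Csf3 by 5.81 ± 0.28 and the anti-inflammatory cytokine Il10 by 4.28 ± 0.21. NF-kB feedback genes and targets rose in 15 of 18 cases (16 adjusted over the list alone), with Tnfaip3 at 4.22 ± 0.17, and STAT3 targets in 12 of 14 with 1 lower (12 and 1 adjusted over the list alone), with Socs3 at 4.07 ± 0.24. The lipopolysaccharide co-receptor Cd14 rose by 7.41 ± 0.24. These lists and the acute phase list kept an adjusted p of 0.0242 with an estimated correlation.

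Among 23 tested cytochrome P450 and drug metabolism genes, 19 fell and 2 rose in the same libraries (20 and 2 adjusted over the list alone), and the list kept an adjusted p of 0.0242 with an estimated correlation. Cyp2c37 fell from 59.1 ± 9.84 to 0.282 ± 0.205 scaled RPKM (log2 change -6.27 ± 0.22), and Cyp1a2 changed by -6.19 ± 0.31. The steroid-converting enzymes Akr1c6 and Hsd3b3 changed by -7.23 ± 0.31 and -5.64 ± 0.16, the carbonic anhydrase Car3 by -6.36 ± 0.25 and the peroxisomal oxidase Hao2 by -6.25 ± 0.16. Bile acid genes fell in 11 of 16 cases and rose in 2 (11 and 2 adjusted over the list alone), led by Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -5.33 ± 0.18. That list had an adjusted p = 0.128 with an estimated correlation. Plasma proteins made by hepatocytes fell in 11 of 19 cases (14 adjusted over the list alone), with the thyroxine carrier Ttr at -2.82 ± 0.2, and an adjusted p = 0.351 with an estimated correlation.

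Proliferation genes fell in all 25 tested cases (25 adjusted over the list alone), with the replication helicase gene Mcm6 at -2.22 ± 0.13 and a list median of -1.45. Genes of the unfolded protein and integrated stress response rose in 18 of 21 cases (18 adjusted over the list alone), with Xbp1 at 1.68 ± 0.12. Both lists had an adjusted p = 0.0761 with an estimated correlation. Monocyte and macrophage markers split, with 4 higher and 12 lower of 20 (4 and 12 adjusted over the list alone) and an adjusted p = 0.438 with an estimated correlation. Marco, a bacterial scavenger receptor, rose by 3.09 ± 0.19, and Vsig4, a complement receptor of Kupffer cells, fell by 3.83 on the log2 scale. By limma, 2646 genes rose and 2615 fell of 12484 tested, and RPKM as deposited split the calls 2089 and 2990.

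Infection of KO-labelled animals moved fewer liver genes past the threshold, 78 higher and 48 lower. The acute phase list led again, with 17 of 27 members higher (22 adjusted over the list alone), a median of 1.07 and an adjusted p = 0.00888 with an estimated correlation. Saa1 rose by 8.32 ± 0.18, Saa2 by 9.42 ± 0.38 and Orm2 by 7.21 ± 0.25. The protease inhibitor A2m rose from 16.2 ± 2.39 to 230 ± 22.1 scaled RPKM (log2 change 3.79 ± 0.32, adjusted p = 1.49e-05, n = 3 per group), the iron-binding protein gene Lcn2 by 2.9 ± 0.28 and the lens crystallin gene Crybb3 by 2.77 ± 0.4. The calcium-binding protein gene S100g changed by -1.98 ± 0.43, Ly6g by -1.89 ± 0.3 and the immunoglobulin gene Iglc2 by -1.85 ± 0.41. STAT3 targets rose in 4 of 14 cases (5 adjusted over the list alone), with Timp1 at 4.21 ± 0.21. Oxidative phosphorylation genes had a median of -0.38, with 0 of 30 passing (18 lower adjusted over the list alone). These 2 lists had an adjusted p = 0.2 with an estimated correlation. Short genes as a class were lower in this comparison (rank correlation of log2 change and length 0.29, shortest 10% -0.21, longest 10% 0.09). The count of 126 became 56 with no filter and 1187 with array quality weights. Left-out libraries gave 192 without control replicate 1, 53 without control replicate 2, 80 without infected replicate 4, 82 without infected replicate 5 and 51 without infected replicate 6. Of the 53, 46 were higher and 7 lower, and of the 51, 43 were higher and 8 lower.

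Uninfected livers differed by genotype label, with 1253 genes higher and 995 lower in the libraries labelled KO. Erythroid genes were higher in all 14 tested cases (14 adjusted over the list alone), with a median of 1.82 and an adjusted p = 0.45 with an estimated correlation. The red cell transcription factor gene Klf1 was higher by 2.37 ± 0.25 and the red cell membrane gene Rhag by 2.08 ± 0.18, and the per-library median of the list was 23.1 to 27.8 scaled RPKM against 7.05 to 9.2. Glycolysis genes were higher in 14 of 25 cases (17 adjusted over the list alone), with Eno1 at 1.52 ± 0.23. Proliferation genes were higher in 11 of 25 (15 adjusted over the list alone), with Mki67 at 0.97 ± 0.16, and oxidative phosphorylation genes in 12 of 30 (17 adjusted over the list alone), with Cox5b at 1.05 ± 0.14. These had adjusted p = 0.45, 0.784 and 0.605 with an estimated correlation. Among single genes with the largest changes were the carboxylesterase Ces1b (2.71 ± 0.15), Rhd (2.58 ± 0.24), Mt2 (2.55 ± 0.44), Cldn13 (2.54 ± 0.21) and Tff3 (2.42 ± 0.35). Hamp, the gene of the iron-regulating hormone hepcidin, was lower by -4.06 ± 0.51 (61.2 ± 39.2 in WT and 3.18 ± 1.99 in KO, adjusted p = 0.000404, n = 3 per group). Cyp2a22 was lower by -4.56 ± 0.22, Ces1g by -1.86 ± 0.2, Hsd3b5 by -1.79 ± 0.35, Sstr2 by -1.7 ± 0.32 and Zfp982 by -1.69 ± 0.29.

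Short genes were higher and long genes lower in this comparison, with a rank correlation of -0.4 between log2 change and length over 12481 genes, which are not independent replicates. The shortest 10% of genes had a median of 0.39 and the longest 10% had -0.26. RPKM as deposited split the calls 596 higher and 2045 lower and put the median of all genes at -0.17. Other counts than 2248 came from array quality weights (3969), Ddx3y as covariate (438) and removal of the length trend (1386). Ddx3y, a gene of the Y chromosome, was high in every WT control and near 0 in KO controls 2 and 3, so it partly coincides with genotype. The sign rests on the labels. Other counts also came without KO control replicates 2 (824) or 3 (715), or WT control replicates 1 (1262), 2 (1444) or 3 (882).

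Among infected livers, 2725 genes were higher and 2674 lower in the libraries labelled KO. Inflammatory cytokines and chemokines were lower in 19 of 20 cases (19 adjusted over the list alone), with Cxcl2 at -5.97 ± 0.24 and Ccl3 at -5.69 ± 0.29, and an adjusted p = 0.0518 with an estimated correlation. Saa3 averaged 13140 ± 3120 scaled RPKM in WT and 74.2 ± 7.02 in KO (log2 difference -7.43 ± 0.34, adjusted p = 8.82e-10, n = 3 per group). Hamp was lower by -7.1 ± 0.51, Cd14 by -6.75 ± 0.24 and the steroid sulfate transporter gene Slc10a6 by -5.68 ± 0.18. Cytochrome P450 and drug metabolism genes were higher in 19 of 23 cases and lower in 2 (20 and 2 adjusted over the list alone), again with an adjusted p = 0.0518 with an estimated correlation. Akr1c6 was higher by 6.49 ± 0.31, Inmt by 5.67 ± 0.35, Car3 by 5.67 ± 0.25, Hsd3b3 by 5.6 ± 0.16, Hao2 by 5.52 ± 0.16 and Cyp2c37 by 5.21 ± 0.22. All 25 proliferation genes were higher (25 adjusted over the list alone), with Mki67 at 2.37 ± 0.16 and an adjusted p = 0.0612 with an estimated correlation. Neutrophil markers were higher in 16 of 20 and lower in 3 (16 and 3 adjusted over the list alone), with the granule genes Ltf at 2.92 ± 0.19 and Mpo at 2.43 ± 0.25, and erythroid markers in 12 of 14 (12 adjusted over the list alone), with Klf1 at 2.59 ± 0.25. These 2 lists had adjusted p = 0.269 and 0.31 with an estimated correlation. The direction rests on the labels, whose Il27ra means in infected liver were alike (1.77 ± 0.793 in KO and 1.67 ± 0.311 in WT), and genotype coincides with the Ec-low wording.

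The infection effect itself differed between genotype labels for 3559 liver genes, 1810 with a higher and 1749 with a lower effect in KO. Saa3 had a difference of effects of -7.45 ± 0.48 (adjusted p = 9.61e-08), and Cd14 of -6.94 ± 0.34. The phosphate hormone gene Fgf23 differed by -5.93 ± 0.49 and Slc10a6, listed at 0 in the 3 WT controls, by -5.77 ± 0.26. On the other side stood Akr1c6 at 7.27 ± 0.43, which fell in WT and averaged 352 ± 127 and 344 ± 36.1 scaled RPKM in KO controls and infected KO. Car3 (6.32 ± 0.35), Cyp2c37 (6.03 ± 0.31), Hao2 (5.8 ± 0.23) and Prok1 (5.82 ± 0.58, listed at 0 in the 3 infected WT libraries) were similar. By list, the effect was lower for 17 of 20 cytokines and chemokines (17 adjusted over the list alone) and higher for 16 and lower for 2 of 23 cytochrome P450 genes (18 and 2 adjusted over the list alone), both with adjusted p = 0.0387 with an estimated correlation. Acute phase genes had a lower effect in 19 of 27 cases (21 adjusted over the list alone), with Saa1 at -3.41 ± 0.25, and glucocorticoid targets in 10 of 13 (10 adjusted over the list alone), with Zbtb16 at -3.14 ± 0.26. Proliferation genes had a higher effect in 25 of 25 (25 adjusted over the list alone). These 3 lists had adjusted p = 0.0678, 0.1 and 0.0679 with an estimated correlation. RPKM as deposited split the calls 2263 higher and 1211 lower, and put the median of all genes at 0.13. Labels alone set the sign, as the Il27ra difference in liver did not pass its test, and short genes had lower values here too (rank correlation 0.2, shortest 10% -0.37, longest 10% 0.17).

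**Figure D2:**
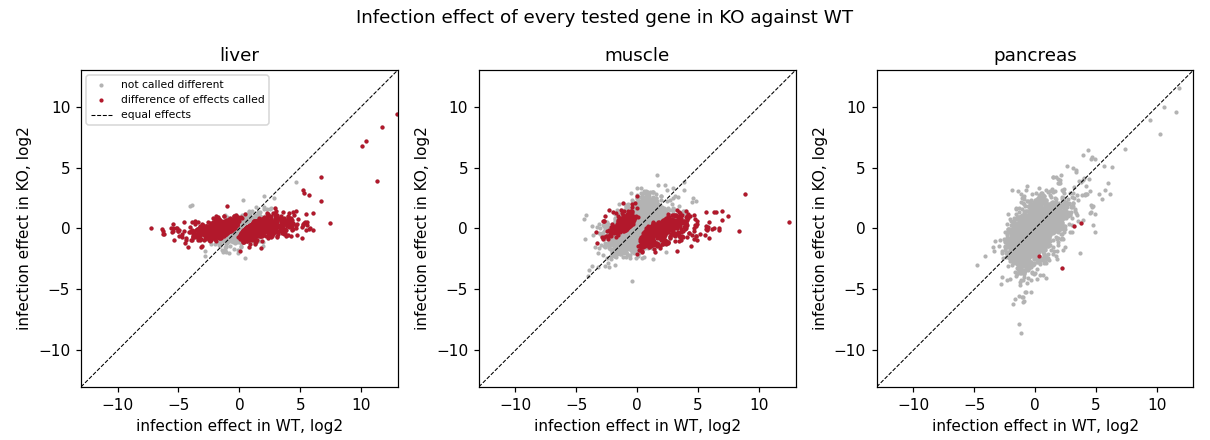
Infection effect (log2) of every tested gene in KO-labelled against WT-labelled libraries for liver, muscle and pancreas, both axes linear in log2. Red points are genes whose effects differed (3559 in liver, 1050 in muscle, 4 in pancreas), and the dashed line marks equal effects.

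Across genes, infection effects of the 2 genotype labels had a Pearson r of 0.27 in liver, 0.26 in muscle and 0.56 in pancreas, with slopes of KO on WT of 0.1, 0.19 and 0.65. Genes are not independent replicates, and the 2 effects share no library. In liver, 65 genes rose in both (16.5 for independent lists) and 30 fell in both (10.1). Without KO control replicate 2 only 46 genes rose and 7 fell in KO liver, and without KO infected replicate 6 only 43 and 8. At most that many could then be shared. In pancreas 19 genes rose in both (0.3 for independent lists), and at most 8 to 10 could without WT infected replicate 1 or 2 or KO infected replicate 2 or 3, when 9, 8, 10 and 9 genes rose in that genotype. The muscle r was 0.11 without the 2 libraries titled in another style, and the pancreas r was 0.04 with the glandular stomach level, which parts the genotypes, as covariate and 0.36 without the 3 libraries highest in Alb.

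Hindlimb muscle of infected WT-labelled animals showed raised inflammatory and atrophy genes. Inflammatory cytokines and chemokines rose in 16 of 18 cases (17 adjusted over the list alone), with Cxcl2 at 6.71 ± 0.26, Ccl4 at 6.14 ± 0.33 and Tnf at 3.61 ± 0.25. Saa3 rose from 0.199 ± 0.201 to 4203 ± 2151 scaled RPKM (log2 change 12.44 ± 0.55, adjusted p = 4.19e-07, n = 3 per group), Lcn2 by 8.88 ± 0.64, Slc10a6 by 8.31 ± 0.43 and Serpina3n by 7.42 ± 0.75. Muscle atrophy and FoxO genes rose in 17 of 22 cases and fell in 1 (19 and 1 adjusted over the list alone), led by Fbxo32, the ubiquitin ligase atrogin-1, at 6.67 ± 0.22. Glucocorticoid targets rose in 11 of 13 (11 higher and 1 lower adjusted over the list alone), with Fkbp5 at 3.98 ± 0.23, and the metallothionein genes Mt1 and Mt2 by 6.95 ± 0.43 and 6.93 ± 0.32. Type I interferon response genes rose in 21 of 26 (23 adjusted over the list alone), with Ifit1 at 3.08 ± 0.25. These 4 lists had an adjusted p = 0.117 with an estimated correlation. Cholesterol synthesis genes fell in 17 of 21 cases (18 adjusted over the list alone), with Sqle at -2.19 ± 0.19 and an adjusted p = 0.247 with an estimated correlation.

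The largest falls in WT-labelled muscle were of Plin1, the fat droplet coat protein gene, at -4.31 ± 0.93, Afp at -3.99 ± 1.13, Ttr at -3.72 ± 0.97, the hair keratin gene Krt71 at -3.69 ± 1.13, Ky at -3.45 ± 0.51 and Apln at -3.4 ± 0.3. Afp and Ttr are hepatocyte products, and the hepatocyte list had a median of 5.23, 5.04 and 17.1 scaled RPKM in WT controls 1 to 3 and 0.382, 0.576 and 2.86 in infected replicates 4 to 6. Krt71 stood at 69.3 in WT control replicate 1 and at 0.491 and 3.73 in replicates 2 and 3. By limma 1614 genes rose and 1292 fell of 13362, and RPKM as deposited split the calls the other way, 1320 and 1575. The count of 2906 became 5128 with array quality weights, 1802 with Ddx3y as covariate, 1931 without WT control replicate 2 and 1756 without infected replicate 6. RPKM as deposited put the median of all genes at -0.11.

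In infected KO-labelled muscle (2 libraries), 0 of 13362 genes passed with limma, while 3196 had an unadjusted p under 0.05 and limma voom also called 0. By camera with the preset correlation 21 of 42 lists were called, and with an estimated correlation 0 were. Myofibre genes had a median of -1.34, with 0 of 24 passing (24 lower adjusted over the list alone), Tcap at -1.32 ± 0.33 and Casq1 at -1.51 ± 0.38. Oxidative phosphorylation genes had a median of -1.09, with 0 of 32 passing (31 lower adjusted over the list alone). Neutrophil markers had a median of 2.23 with 0 of 18 passing (4 higher adjusted over the list alone), with S100a8 at 2.5 ± 0.57. The first 3 lists had an adjusted p = 0.47 with an estimated correlation. Cartilage and bone markers had a median of 2.96 with 0 of 11 passing (1 adjusted over the list alone) and an adjusted p = 0.524 with an estimated correlation. The erythroid list median was 14.2 and 12.1 scaled RPKM in the infected KO libraries and 4.57, 6.71 and 1.08 in KO controls. Tissue content thus moved along with the lists above. The smallest p-values belonged to Slc35e3 (1.02 ± 0.17), Slc22a17 (0.96 ± 0.16) and H2-Pb (2.67 ± 0.47), and to Lmod2 (-1.57 ± 0.24), Crym (-2.22 ± 0.35) and the myogenic factor gene Myf5 (-1.41 ± 0.23), all at an adjusted p of 0.112. No filter gave 6 genes, array quality weights 4039, omission of infected replicate 4 gave 52 and of control replicate 2 gave 1. The 52 compare a single infected library with the controls, and the other groups supply the spread. RPKM as deposited put the median of all genes at 0.19.

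Control muscle differed between genotype labels in 3 genes, named here because so few passed. Wdfy1, an endosomal adaptor gene, was higher in the libraries labelled KO (12.3 ± 0.69 against 1.93 ± 0.338 scaled RPKM, log2 difference 2.41 ± 0.14, adjusted p = 5.92e-05, n = 3 per group). Ucma, a cartilage matrix gene, was higher by 6.4 ± 0.7 (adjusted p = 0.0123), and Scoc, a Golgi protein gene, was lower by -1.35 ± 0.16 (adjusted p = 0.0218). Values that did not pass were 4.26 ± 0.59 for Scrg1, -0.91 ± 0.16 for Ifrd1 and -3.31 ± 0.69 for Krtap8-1. Cartilage and bone markers had a median of 4.55 with 0 of 11 passing (10 adjusted over the list alone), with Col2a1 at 7.73 ± 1.25, and neutrophil markers a median of 2.01 with 0 of 18 passing (4 adjusted over the list alone). Both had an adjusted p = 0.604 with an estimated correlation. Only Wdfy1 was left, with 1 gene called, when the model had Ddx3y as covariate or the 2 groups alone, or under limma voom, or without the 2 libraries titled in another style. Other counts were 6 (pseudocount 0.1), 5402 (array quality weights), 6 (cartilage covariate) and 5 (thinned reads). Leaving out KO control replicates 1 or 2, or WT control replicates 1 or 3, gave 1, and leaving out KO control replicate 3 gave 215.

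Infected muscle differed between genotype labels in 2282 genes higher and 2304 lower in KO. All 11 cartilage and bone markers were higher (11 adjusted over the list alone; adjusted p = 0.488 with an estimated correlation). Col2a1, the main cartilage collagen gene, averaged 3712 ± 851.3 scaled RPKM in 2 KO libraries and 6.589 ± 9.645 in 3 WT libraries (log2 difference 10.24 ± 1.39, adjusted p = 0.000528). The cartilage genes Matn1 (9.52 ± 1.31), Cnmd (9.18 ± 1.16), Col9a1 (9.01 ± 1.37), Col9a3 (8.47 ± 1.17) and Snorc (8.35 ± 1.06) followed. Myofibre genes were lower in 15 of 24 cases (17 adjusted over the list alone), with Atp2a1, the calcium pump of fast fibres, at -2.21 ± 0.41 and an adjusted p = 0.51 with an estimated correlation. Saa3 was lower by -11.95 ± 0.61, Slc10a6 by -8.68 ± 0.48, Cxcl1 by -6.44 ± 0.6 and Serpina3n by -6.25 ± 0.83. Cxcl2 and Acod1, an antibacterial itaconate enzyme gene, were listed at 0 in both KO libraries and averaged 59.7 ± 18.8 and 41.4 ± 16.5 in WT. Atrophy and FoxO genes were lower in 18 of 22 (19 adjusted over the list alone), with Trim63 at -6.12 ± 0.39, and type I interferon genes in 20 of 26 (23 adjusted over the list alone), with Ifit3 at -3.0 ± 0.35. Both had an adjusted p = 0.328 with an estimated correlation.

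The cartilage level moved together with these groups in infected muscle, at a list median of 276 and 288 scaled RPKM in the KO-labelled libraries and 0.0512 to 4.67 in WT. That level nearly coincides with genotype here, so a fit with it as covariate has little left to compare and says nothing of the cause. It called 139 genes instead of 4586, with Saa3 at -9.84 (-11.95 without it) and Fbxo32 at -4.88 (-5.74 without it). Leaving out KO infected replicate 4 gave 2690 and replicate 6 gave 1968, and RPKM as deposited split the calls 3556 higher and 1393 lower with the median of all genes at 0.29. The direction rests on labels that Il27ra goes against if its value reads the deleted part, and the Ec-low wording applies.

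The infection effect in muscle differed between genotype labels for 1050 genes, 329 with a higher and 721 with a lower effect in KO. Saa3 differed by -11.94 ± 0.82 (adjusted p = 3.17e-05), Slc10a6 by -8.54 ± 0.64 and Cxcl2 by -6.82 ± 0.4. Pdk4, which blocks glucose oxidation, differed by -6.67 ± 0.45, with 25.3 ± 6.51 and 1521 ± 465.3 scaled RPKM in control and infected WT and 45.6 ± 16.2 and 25.3 ± 4.5 in KO. Fbxo32 differed by -6.6 ± 0.34. Cytokines and chemokines had a lower effect in 16 of 18 cases (16 adjusted over the list alone) and glucocorticoid targets in 11 of 13 (11 adjusted over the list alone), both with adjusted p = 0.0856 with an estimated correlation. Atrophy genes had a lower effect in 14 of 22 (16 adjusted over the list alone; adjusted p = 0.173 with an estimated correlation). Cholesterol synthesis genes had a higher effect in 11 of 21 (17 adjusted over the list alone; adjusted p = 0.31 with an estimated correlation), with Sqle at 2.29 ± 0.29. Higher effects were also seen for the desaturase gene Scd2 (3.67 ± 0.77), Spon2 (3.42 ± 0.51), Frzb (3.4 ± 0.44) and Rcor2 (3.39 ± 0.61). The cartilage list median was 84.5, 105 and 2.02 scaled RPKM in KO controls and 276 and 288 in infected KO. Tissue content may therefore enter these higher effects.

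RPKM as deposited split these muscle calls 531 higher and 531 lower, with the median of all genes at 0.26. Among the counts that moved beyond 1.5 times were those from array quality weights (4279), Ddx3y as covariate (593), the cartilage covariate (699), and omission of the 2 libraries titled in another style (1607), KO control replicate 1 (630), KO infected replicates 4 (518) or 6 (441; 1 library left in that group in either case), WT control replicate 2 (627) or WT infected replicate 6 (617). With the title style as a batch term the count was 1179, and the sign rests on the labels, with the reserve about Il27ra given above.

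**Figure D3:**
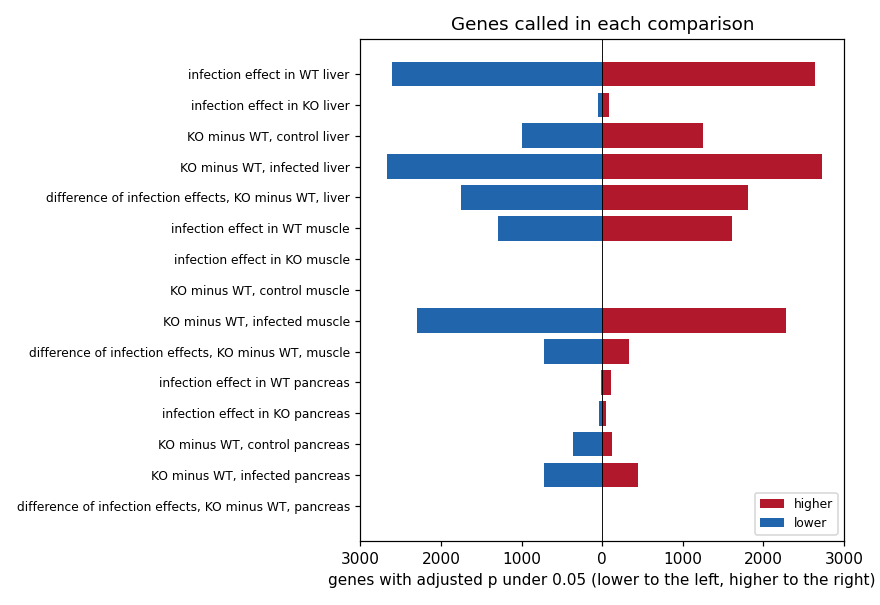
Number of genes with an adjusted p under 0.05 in each of 15 comparisons, lower to the left in blue and higher to the right in red. Infected liver between genotypes has the most calls (5399), and infection in KO muscle has 0.

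The receptor chain Il6st and the ligand subunit Ebi3 rose with infection in WT-labelled liver, by 1.29 ± 0.19 (adjusted p = 6.18e-05) and 1.19 ± 0.22 (adjusted p = 0.000514). In WT-labelled muscle they rose by 1.49 ± 0.16 and 1.62 ± 0.26. The difference of effects was -1.05 ± 0.26 and -1.26 ± 0.31 in liver and -1.62 ± 0.23 and -1.43 ± 0.39 in muscle, with adjusted p = 0.00862, 0.00726, 0.00258 and 0.0497. Pancreas values did not pass, at 0.85 ± 0.22 and 0.9 ± 0.34 in WT. Il27 was tested in liver only, at 0.51 ± 0.49 in WT (adjusted p = 0.431).

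In WT-labelled pancreas, infection raised the Reg family, secreted lectins of the acinar stress response. Of 7 members 4 rose (5 adjusted over the list alone), with an adjusted p = 0.147 with an estimated correlation. Reg3b rose from 0.439 ± 0.119 to 3886 ± 2602 scaled RPKM (log2 change 11.84 ± 0.56, adjusted p = 2.68e-05, n = 3 and 2), Reg2 by 10.58 ± 0.65, Reg3g by 10.21 ± 0.42 and Reg3a by 9.44 ± 0.54. Saa3 rose by 11.6 ± 0.69 and Serpina3n by 7.37 ± 1.33. Cytokines and chemokines rose in 10 of 19 cases (16 adjusted over the list alone), with Cxcl5 at 4.79 ± 0.45 and Ccl2 at 4.26 ± 0.48, and NF-kB genes in 3 of 18 (17 adjusted over the list alone), with Nfkbiz at 1.64 ± 0.18. Cholesterol synthesis genes fell in 2 of 22 (14 adjusted over the list alone), with Cyp51 at -1.37 ± 0.19. These 3 lists had an adjusted p = 0.147 with an estimated correlation. Falls were largest for Thbs2 (-2.29 ± 0.26), Spon2 (-2.26 ± 0.4), Cyp2c55 (-2.07 ± 0.34), Apln (-1.95 ± 0.3), Upk3a (-1.95 ± 0.28) and Scd2 (-1.92 ± 0.29). Markers of other tissues, in lists written after the data were seen, moved as well. Medians were -1.44 for milk protein, -1.13 for smooth muscle, -0.98 for squamous and 0.46 for glandular stomach genes, with 1 stomach gene called higher.

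Of 15138 pancreas genes 108 rose and 15 fell in that comparison. The 123 calls became 2922 with array quality weights, 2241 with the 2 groups alone, 297 without the 3 libraries highest in Alb, 18 with Ddx3y and 41 with the stomach level as covariate. Without WT control replicates 1, 2 or 3 they were 18, 21 or 10, and without infected replicates 1 or 2, which leaves 1 infected library, they were 9 or 8.

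Infected KO-labelled pancreas showed the Reg response too, with 5 of 7 members higher (6 adjusted over the list alone; adjusted p = 0.381 with an estimated correlation). Reg3b rose by 11.5 ± 0.5 (adjusted p = 2.52e-05, n = 3 per group), Reg2 by 9.95 ± 0.58 and Reg3d by 3.38 ± 0.54. Acute phase genes rose in 2 of 27 cases (25 adjusted over the list alone), namely Saa3 by 9.59 ± 0.62 and C3 by 2.88 ± 0.38, with an adjusted p = 0.482 with an estimated correlation. Plasma proteins of hepatocytes moved with this list in some libraries, with a median of 13.2, 15.8 and 17.2 scaled RPKM in controls and of 2.1, 112 and 108 in infected replicates 1 to 3. The scavenger receptor gene Marco rose by 4.18 ± 0.72 and the dicarboxylate transporter gene Slc13a3 by 3.8 ± 0.4. Keratins of squamous epithelium fell, Krt13 by -8.55 ± 1.32, Krt4 by -7.88 ± 1.17 and Krt15 by -6.23 ± 1.09. Markers of other tissues, in lists written after the data were seen, moved with them, with 4 of 6 milk protein genes (median -2.82) and 2 of 8 smooth muscle genes (median -2.89) lower. The keratinocyte list had a median of -3.4 with 1 of 10 lower (5 adjusted over the list alone; adjusted p = 0.482 with an estimated correlation). Krt13 stood at 436, 29.1 and 2810 scaled RPKM in KO controls 1 to 3. With 46 genes higher and 36 lower, the split was 74 and 35 of 109 after quantile normalization. The count was 51 for RPKM as deposited, 23 with array quality weights, 10 with Ddx3y, 2 with the stomach covariate, 38 without the 3 libraries highest in Alb, 22 under limma voom and 5 with the 2 groups alone. It was 860, 446 or 300 without control replicates 1, 2 or 3, 577 without infected replicate 1, and 16 without infected replicate 2 or 3.

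Control pancreas libraries labelled KO held less of a group of stomach genes. Gkn2 averaged 3172 ± 307.2 scaled RPKM in WT and 12.31 ± 12.45 in KO (log2 difference -8.39 ± 0.76, adjusted p = 0.000314, n = 3 per group). Gkn1 was lower by -7.75 ± 0.65 and Tff1 by -7.54 ± 0.56, both products of gastric surface cells, and Atp4b, the acid pump subunit of parietal cells, by -6.89 ± 0.39. Mucl3 and Bpifb1 were lower by -7.67 ± 0.2 and -6.9 ± 0.57. Islet endocrine markers were higher in 7 of 24 cases (13 adjusted over the list alone), with the insulin genes Ins1 at 2.22 ± 0.37 and Ins2 at 2.21 ± 0.42, Mafa at 2.56 ± 0.37 and Ppy at 1.84 ± 0.26. Acinar markers split into 1 higher and 1 lower of 31 (15 and 1 adjusted over the list alone), Ctrc at 1.67 ± 0.36 and Pla2g1b, which the stomach also makes, at -3.41 ± 0.45. Both lists had an adjusted p = 0.92 with an estimated correlation. The acinar list median was 460, 279 and 584 scaled RPKM in WT controls and 962, 1240 and 1060 in KO controls. Because stomach genes were high in the WT libraries, a lower share of pancreas RNA there cannot be told from a rise in KO. Pcsk1n (2.48 ± 0.41), Igfbp6 (2.11 ± 0.45) and Il27ra (2.07 ± 0.27) were also higher.

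The control pancreas comparison called 126 genes higher and 368 lower in KO, and RPKM as deposited split them 70 and 396 of 466. The 494 calls became 324 with array quality weights, 158 with the 2 groups alone and 0 with the stomach level as covariate, which parts the genotypes completely and so leaves nothing to compare. Leaving out WT control replicates 1, 2 or 3 gave 176, 178 or 152, and leaving out KO control replicates 1, 2 or 3 gave 820, 1453 or 1193. The direction rests on the labels, and Il27ra itself was higher in KO-labelled pancreas.

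Infected pancreas repeated the stomach difference, with Tff1 at 5788 ± 749.1 scaled RPKM in 2 WT libraries and 4.26 ± 3.37 in 3 KO libraries (log2 difference -10.47 ± 0.62, adjusted p = 1.5e-05). The milk-clotting enzyme gene Cym was lower by -10.06 ± 0.59, Gkn2 by -9.95 ± 0.85, Bpifb1 by -9.54 ± 0.64, Sprr2a3 by -9.52 ± 0.39 and Gkn1 by -9.47 ± 0.73. Acinar markers were higher in 17 of 31 cases and lower in 1 (29 and 1 adjusted over the list alone), with Rbpjl at 3.07 ± 0.5, and islet markers in 9 of 24 (16 adjusted over the list alone), with Ins2 at 3.05 ± 0.47. Monocyte and macrophage markers were higher in 9 of 18 (11 adjusted over the list alone), with the complement gene C1qa at 2.47 ± 0.28. Cytokines and chemokines were lower in 6 of 19 (10 adjusted over the list alone), with Cxcl5 at -4.14 ± 0.45 and Ccl20 at -4.19 ± 0.47, and keratinocyte markers in 3 of 10 (10 adjusted over the list alone), with Krt5 at -7.19 ± 1.62. These 5 lists had an adjusted p = 0.606 with an estimated correlation. The acinar list median was 508 and 161 scaled RPKM in infected WT and 2600, 1580 and 890 in infected KO. As in controls, a lower share of pancreas RNA in WT cannot be told from a rise of acinar or islet genes in KO. The glandular stomach median was 287 and 225 scaled RPKM in infected WT and 1.04, 0.533 and 0.933 in infected KO. The lower cytokine and chemokine genes and the higher macrophage markers cannot be told from this difference in tissue content either. Haemoglobin Hbb-b1 was higher by 4.37 ± 1.1, the T cell receptor genes Trbj2-3 and Trbc2 by 3.96 ± 0.94 and 3.13 ± 0.38, and the hepatocyte products Vtn and Ambp by 3.67 ± 0.51 and 3.18 ± 0.62, with Gc among the 6 largest rises too. Alb, another hepatocyte product, stood at 1700 and 1590 scaled RPKM in infected KO replicates 2 and 3 and at 22.5 in replicate 1.

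With 444 genes higher and 721 lower in KO, infected pancreas had 1165 calls. They became 5501 with array quality weights, 2417 with the 2 groups alone, 0 with the stomach covariate (void here for the same reason), 497 or 233 without WT infected replicate 1 or 2 (1 WT infected library left, the spread coming from the other groups), and 652 without KO infected replicate 2. Genotype labels give this direction, and Il27ra runs against them in pancreas if its value reads the deleted part.

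**Figure D4:**
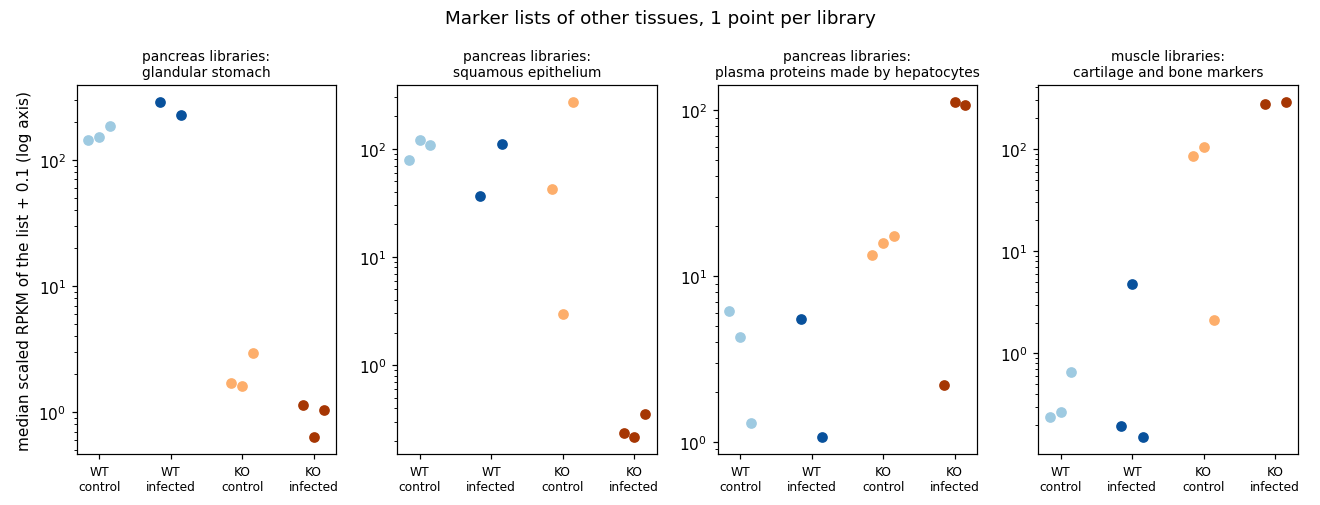
Median scaled RPKM plus 0.1 (log axis) of 4 marker lists, 1 point per library. In pancreas the glandular stomach list lies between 143 and 287 in WT-labelled and between 0.533 and 2.82 in KO-labelled libraries, and in muscle the cartilage and bone list reaches 276 and 288 in infected KO libraries.

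The infection effect in pancreas differed between genotype labels for 4 genes, given because so few passed. Sprr2a3, a squamous epithelium gene, had a difference of effects of -5.44 ± 0.53 (adjusted p = 0.0324), with 95.5 ± 16.2 and 433 ± 48.7 scaled RPKM in control and infected WT and 5.84 ± 3.99 and 0.0908 ± 0.0788 in KO. The mucosal chemokine gene Cxcl17 differed by -3.3 ± 0.36, Foxf2, a transcription factor of gut mesenchyme, by -2.54 ± 0.28, and the proton pump subunit gene Atp6v0d2 by -2.98 ± 0.35. The squamous list median was 42.5, 2.88 and 271 scaled RPKM in KO controls and 0.136, 0.115 and 0.253 in infected KO. In WT the glandular stomach median was 143, 150 and 185 in controls and 287 and 225 in infected libraries. The WT squamous median was 78, 121 and 109 in controls and 36.4 and 110 in infected libraries. The rise of Sprr2a3 in WT thus did not go with squamous content, while the stomach median was higher. Otherwise the 4 differences cannot be told from such changes in tissue content. Values that did not pass were 1.94 ± 0.35 for Thbs2, 2.29 ± 0.42 for Scd1 and 2.11 ± 0.41 for Bpifb5. Cytokines and chemokines had a median of -1.45 with 0 of 19 passing (4 adjusted over the list alone; adjusted p = 0.542 with an estimated correlation). Immediate early genes had a median of -1.22 with 0 of 13 passing (1 adjusted over the list alone; adjusted p = 0.439 with an estimated correlation). The 4 calls became 1 or 9 with pseudocounts of 0.1 or 1, 8 with no filter, 24 with array quality weights, 38 without the 3 libraries highest in Alb, 12 with thinned reads, and 0 with RPKM as deposited, Ddx3y, the stomach covariate or limma voom, where limma had 760 genes at an unadjusted p under 0.05. Leaving out KO control replicates 1 or 2 gave 50 or 20 and KO infected replicate 1 gave 25, while 0 remained without WT control replicates 1, 2 or 3, WT infected replicates 1 or 2, or KO infected replicates 2 or 3.

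Infection raised a shared set of genes across WT-labelled tissues. Of 11662 genes tested in all 3 tissues, 56 rose in all 3 (2.26 for independent lists), among them Saa3, Il6, Il1b, Cxcl2, Ccl2, Socs3, Tnfaip3 and Cd14, picked here from that set after it was seen. Only Cx3cr1, a chemokine receptor gene of resident macrophages, and Spon2 fell in all 3 (0.12 for independent lists). Leaving out any 1 WT pancreas library left 8 to 19 genes that rose and 0 to 2 that fell in that tissue, so at most that many could be shared. Liver and muscle shared 813 genes that rose (318 for independent lists) and 438 that fell (200). Ddx3y matched between liver and muscle for each WT number. These tissues may therefore share animals, and the values for independent lists may not apply. Ddx3y also partly coincided with infection in WT in both tissues. With it as covariate, fewer genes were called in the same direction in at least 2 WT tissues. Between infected genotypes, 43 genes were higher (9.98) and 61 lower (14.9) in KO-labelled libraries of all 3 tissues, a direction that rests on the labels. In liver and muscle the genotype label also coincides with the Ec-low wording. Cartilage markers in muscle and stomach markers in pancreas differ between the genotype labels too. The 43 and 61 genes cannot be told from these. Without pancreas WT infected replicate 2 only 30 genes were higher in infected KO pancreas, so the 43 would not hold.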

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

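The tests of stomach tissue, of cartilage dilution, of the Ec-low wording and of linkage were chosen after the results were seen. The tests of gene length and depth use alternatives added after the data were examined, though before their own results were seen. Regrouping of libraries was set beforehand. The genes and lists in the next paragraph differed between genotype labels in the effect of infection, tested as the difference of the 2 effects in limma. Signs rest on the labels, and Il27ra runs against these in muscle and pancreas if its value reads the deleted part.

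In liver 3559 genes and 24 gene lists differed, 5 of the lists also with an estimated correlation. Among the genes with the largest differences were Akr1c6 (7.27), Car3 (6.32), Cyp2c37 (6.03), Prok1 (5.82) and Hao2 (5.8), and on the other side Saa3 (-7.45), Cd14 (-6.94), Fgf23 (-5.93) and Slc10a6 (-5.77). In muscle 1050 genes and 22 lists differed, 0 of the lists with an estimated correlation. The muscle genes included Scd2 (3.67), Spon2 (3.42), Frzb (3.4) and Rcor2 (3.39) against Saa3 (-11.94), Slc10a6 (-8.54), Cxcl2 (-6.82), Pdk4 (-6.67) and Fbxo32 (-6.6). The cartilage list median was higher in infected than in control KO-labelled muscle, so tissue content may enter the higher effects. In pancreas 4 genes and 21 lists differed, 0 of the lists with an estimated correlation, and the genes were Sprr2a3 (-5.44), Cxcl17 (-3.3), Atp6v0d2 (-2.98) and Foxf2 (-2.54). The squamous median was lower in infected than in control KO-labelled pancreas, and the stomach median was higher in infected than in control WT-labelled pancreas. The squamous median did not rise in WT, where Sprr2a3 did. Otherwise these 4 genes cannot be told from such changes in tissue content.

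Glandular stomach genes were lower in KO-labelled pancreas libraries, in 18 of 20 tested cases among infected animals. The difference of infection effects had a list median of -1.12 (camera p = 0.00504, unadjusted, with an estimated correlation) with 0 of 20 genes passing. The list was written after these data were seen, so that p gives no independent support. Stomach tissue taken along with the WT pancreas is a candidate explanation. Of the 15 list members that the rule did not name, 13 were lower too, though they come from the same list. Other lists were also lower in infected KO libraries, squamous epithelium in 8 of 11 cases (median -6.31), smooth muscle in 5 of 8 (-3.69) and milk proteins in 5 of 6 (-3.08), while KO control 3 had more squamous signal (271) than any WT library (36.4 to 121), so more than glandular stomach may be involved. Gene length is an unlikely explanation, as the list median was -7.11 after the length trend was removed and -7.13 before. A difference of genotype in the pancreas itself was not tested and stays open, because every WT library was high and every KO library low.

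Cytokine and chemokine genes had a smaller infection effect in KO-labelled muscle. Cartilage and bone tissue could dilute muscle RNA in the KO libraries (median marker level 276 and 288 infected; 84.5, 105 and 2.02 in controls, against at most 0.551 in WT controls), and myofibre genes had a median difference of -1.44. The upper quartile of the cytokine genes that rose in WT was -2.87, so dilution is unlikely to be the whole cause. These genes were picked by their rise in WT, which enters the difference with a minus sign, and the myofibre genes were not so picked. A lower bacterial dose or load is possibly what Ec-low stands for, with 0 WT and 5 KO libraries carrying it, and the design cannot separate it from genotype. Loss of interleukin-27 signalling might also give a smaller response. In pancreas, where infected titles of both genotypes carry Ec, the slope of KO on WT infection effects was 0.65. It was 0.1 in liver and 0.19 in muscle, where infected KO titles carry Ec-low. The tissues differ along with the wording, and markers of other tissues part the genotypes in pancreas, so these values do not settle the cause.

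The smaller infection effect in KO-labelled liver might come from gene length or depth. Removing the length trend left 3499 genes and thinning reads left 3307, against 3559, so both are unlikely. Genotype and a milder infection both remain possible explanations, as the same titles carry Ec-low.

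Regrouping the same 6 libraries in all 10 ways gave a count as large only for the real grouping, 1 of 10, which cannot fall under 0.1. This held for infection in WT liver (5261, highest other 1), infection in KO liver (126, highest other 0), control liver (2248, highest other 16), infected liver (5399, highest other 1), WT muscle (2906, highest other 0), control muscle (3, highest other 0), KO pancreas (82, highest other 1) and control pancreas (494, highest other 0). For the difference of effects in liver, 2 of 100 drawn splits out of 200 reached the real count of 3559. The other one, with 5431, exchanges the genotype labels among infected animals only, and the next split had 3117. The exchanged split compares all WT-labelled with all KO-labelled libraries, so its count reflects genotype itself. Other splits can take in part of that genotype difference. The splits therefore do not show what count would arise without a difference of effects, and no conclusion is drawn from the 2 of 100.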

How the results depend on the processing

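Some alternatives were added after the data were examined, namely limma voom, thinned reads, the length trend, both marker covariates, and leaving out libraries by Alb or by title style. Tests under the other alternatives were set before the data were examined. Where a value below differs from the first one given, the cause was not tested, except that fewer libraries leave less power. Quantile normalization kept 15 of 15 counts within 1.5 times, pseudocount 1 kept 14, the length trend 14, pseudocount 0.1, thinned reads and RPKM as deposited 13 each, no filter and limma voom 12 each, Ddx3y 8 and array quality weights 4. Of fewer counts, the 2 groups alone kept 7 of 12, the replicate block 5 of 11, leaving out the title-style libraries 3 of 5 and leaving out the Alb libraries 2 of 5. The batch term for title style kept 5 of 5, the cartilage covariate 2 of 5 and the stomach covariate 0 of 5. Over named genes, 7521 values stayed the same, 516 were weaker, 111 stronger, 39 moved and 13 reversed.

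Infection in KO liver (126) gave 56 with no filter and 1187 with array quality weights. Control liver (2248) gave 3969 with weights, 438 with Ddx3y and 1386 without the length trend. WT muscle (2906) gave 5128 with weights and 1802 with Ddx3y, and KO muscle (0) gave 6 with no filter and 4039 with weights. Control muscle (3) gave 6 with pseudocount 0.1 and with the cartilage covariate, 5402 with weights, 5 with thinned reads, and 1 with Ddx3y, the block, limma voom, the 2 groups alone or without the title-style libraries. Infected muscle (4586) gave 139 with the cartilage covariate. The muscle difference of effects (1050) gave 4279 with weights, 593 with Ddx3y, 1997 with the block, 699 with cartilage and 1607 without the title-style libraries.

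WT pancreas (123) gave 2922 with weights, 18 with Ddx3y, 12 with the block, 41 with the stomach covariate, 297 without the libraries highest in Alb and 2241 with the 2 groups alone. KO pancreas (82) gave 51 as deposited, 23, 10, 19, 2, 38 and 5 in that order, and 22 with limma voom. Control pancreas (494) gave 324 with weights, 263 with the block, 0 with stomach and 158 with the 2 groups. Infected pancreas (1165) gave 5501 with weights, 0 with stomach and 2417 with the 2 groups. The pancreas difference (4) gave 1 and 9 with pseudocounts 0.1 and 1, 8 with no filter, 24 with weights, 38 without the Alb libraries, 12 thinned, and 0 as deposited, with Ddx3y, the block, stomach or limma voom.

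The stomach level parts the genotypes completely in pancreas and the cartilage level nearly does in infected muscle. Counts lost between genotypes there follow from the fit and bear on no cause. Counts for infection within a genotype also fell with the stomach level in pancreas, and why was not tested. Reversed signs came with the stomach covariate only. In control pancreas these were Gkn2 (0.82), Tff1 (3.69), Bpifb1 (6.86), Atp4b (2.04), Pla2g1b (0.6) and Ppy (-2.73). In infected pancreas they were Ambp (-0.98), Tff1 (3.4), Cym (4.12), Gkn2 (1.42), Bpifb1 (7.46), Krt5 (6.86) and Krt15 (6.63), all not passing.

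The agreement r in liver (0.27) was 0.24 with pseudocount 0.1, weights or Ddx3y, 0.29 with pseudocount 1 or without the length trend, and 0.23 with limma voom. In muscle (0.26) it was 0.2 with weights, 0.11 without the title-style libraries and 0.32 with limma voom, and in pancreas (0.56) 0.04 with stomach and 0.36 without the Alb libraries. Genes called in the same direction in at least 2 WT tissues and in no tissue in the other (1270) were 3110 with weights and 741 with Ddx3y. List calls (300) were 12 with an estimated correlation.

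Leaving out 1 library gave lowest and highest counts of 4330 and 4985 (WT liver), 51 and 192 (KO liver), 715 and 2913 (control liver), 4355 and 5308 (infected liver), 2837 and 3758 (liver difference), 1756 and 2891 (WT muscle), 0 and 52 (KO muscle), 1 and 215 (control muscle), 1968 and 4454 (infected muscle), 441 and 1383 (muscle difference), 8 and 21 (WT pancreas), 16 and 860 (KO pancreas), 152 and 1453 (control pancreas), 233 and 997 (infected pancreas), and 0 and 50 (pancreas difference). The r ranged from 0.23 to 0.29, 0.18 to 0.32 and 0.38 to 0.66.

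Same-numbered libraries were not taken as paired, since not every correlation exceeded 0.1. Correlations of their deviations were 0.02 to 0.2 in liver (4 of 6 over 0.1), 0.04 to 0.28 in muscle (3 of 5) and -0.59 to 0.29 in pancreas (5 of 15). A library deviated most like the one of its own number in 10 of 12 checks in liver, 8 of 10 in muscle and 9 of 30 in pancreas, which leans towards pairing in liver and muscle. Depth was lowest in infected KO muscle, at 3.95 to 4.89 M reads.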

Other observations

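The test of genes near Il27ra was run, and its prediction written, after the data were seen. Lists in this part were not described above.

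Genes of the interleukin-27 pathway rose in 8 of 13 cases in WT-labelled liver (8 adjusted over the list alone; adjusted p = 0.0761 with an estimated correlation). The difference of effects was lower for 7 of 13 (7 adjusted over the list alone; adjusted p = 0.0679 with an estimated correlation). Endothelial activation genes rose in 11 of 15 and fell in 2 (11 and 2 adjusted over the list alone), and kept an adjusted p of 0.0242 with an estimated correlation. Hypoxia response genes rose in 9 of 15 and fell in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.222 with an estimated correlation). In WT-labelled muscle, interferon gamma response genes rose in 18 of 31 (19 adjusted over the list alone; adjusted p = 0.247 with an estimated correlation). Fatty acid oxidation genes were lower in infected KO-labelled muscle in 15 of 25 cases and higher in 1 (17 and 1 adjusted over the list alone; adjusted p = 0.502 with an estimated correlation). Those KO libraries were also high in cartilage markers and lower in myofibre genes, so tissue content cannot be told from a change in fatty acid oxidation genes. Lipogenesis genes fell in 9 of 20 and rose in 1 in WT-labelled muscle (13 and 1 adjusted over the list alone; adjusted p = 0.707 with an estimated correlation).

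Ddx3y, a gene of the Y chromosome, describes the samples. In liver it stood at 24.9, 38.5 and 40 scaled RPKM in WT controls 1 to 3 and at 29.8, 0.25 and 0 in infected WT replicates 4 to 6, and muscle had 36.8, 46.3 and 51.3, and 39.3, 0 and 0.0332. KO-labelled controls 1 to 3 had 22.7, 0.0475 and 0 in liver and 0, 28.9 and 0.0812 in muscle. Infected KO replicates 4, 5 and 6 had 0.0349, 28.8 and 20 in liver, and replicates 4 and 6 had 23.7 and 0 in muscle. Ddx3y was thus high or low in both tissues for each number in WT and for KO control 3, and differed between tissues for the other 4 KO numbers held by both. It was high in all WT controls of liver and muscle and low in infected WT replicates 5 and 6 and in most KO controls. In these tissues Ddx3y therefore partly coincides with infection in WT and with genotype in controls.

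Lower values in every KO-labelled than in every WT-labelled library of all 3 tissues were seen for 8 of 11662 genes (0.377 for independent tissues), Arhgap5, Tead1, Scoc, Slmap, Csnk1a1, Aff4, Nbeal1 and Rab5a, and higher values for 0 (0.514). Liver and muscle libraries may share animals, as Ddx3y matched for each WT number, so the values for independent tissues may not apply. Long genes were also lower in KO-labelled controls of liver, muscle and pancreas (rank correlations with length -0.4, -0.16 and -0.16). Among infected animals these were -0.05, 0 and -0.12. Whether gene length plays a part for the 8 genes was not tested. Within 10 Mb of Il27ra, 2 of 103 genes (1.94%) separated in the same direction in at least 2 tissues, against 149 of 11531 (1.29%) elsewhere (Fisher exact p = 0.387, odds ratio 1.51, 95% interval 0.179 to 5.7). These were Mcm5 and Scoc, and the interval is too wide to tell whether sequence linked to the targeted gene might play a part.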
